A study of Rattus norvegicus with 12 samples.

How the data were processed

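Gene expression was measured in 12 libraries of rat H9c2 cells, 3 in each of 4 groups (control, MMA, FA and MMA+FA). Per the labels, RNA was extracted with TRIzol and libraries were made from 1 µg of RNA with the Illumina Stranded mRNA Prep kit. Per the submitters' processing notes, reads were trimmed with fastp and aligned with HISAT2 to the rat build mRatBN7.2. Versions, settings, the annotation release and the strand setting are not given in the sources used here. The deposited values are TPM per gene, made by the authors before deposit, and RSEM is named only in the title of the table. The table held 30562 genes of 19 biotypes, 4380 of them without a symbol, and all of its 12 sample columns were used. Read counts were not used here, so neither the depth of a library nor the counting error of a gene is known.

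What was computed from these values is as follows. Genes with a mean of at least 1 TPM over the 12 libraries were kept (12263 genes), and log2(TPM + 1) was fitted in limma (version 3.58.1, R 4.3.3, with the package data.table in version 1.17.8) with 1 mean per group and a mean-variance trend. The fit had 8 residual degrees of freedom and a prior of 4.317. The comparisons were MMA, FA and MMA+FA each against control, MMA+FA against MMA, MMA+FA against FA, and the interaction, together with an F test across the 4 groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Folds on this scale are log2 differences of group means with limma's standard error. Group values are given as mean and SD of TPM. A permutation of 3 against 3 libraries cannot reach a p below 0.1, so single genes were judged by limma alone. The groups, comparisons, threshold, filter, gene lists and the settings to be varied were chosen before the data were examined.

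Gene lists were written from general knowledge, 40 in all, on folate and cobalamin metabolism, mitochondria, redox and stress responses, lipids and sugars, the cell cycle, inflammation, matrix, muscle, other cell types and housekeeping complexes. The list of histone genes was meant as a check of polyA selection, and the capture of these transcripts was not tested. The 37 lists with at least 5 tested members were tested with camera in limma at its preset correlation between genes of 0.01, which asks whether members rank higher or lower than other genes. Each was also tested with the correlation estimated from the residuals, and with fry. A symbol of a list that belongs to several identifiers (362 symbols in the table do) was taken at the locus with the highest mean TPM. Pathways of KEGG as annotated in the table were tested the same way, an addition made after the data were seen.

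Genes were named by a rule. In each comparison these were called genes with a symbol and a higher group mean of at least 5 TPM, whose libraries did not overlap between the groups, the 12 largest in each direction. For the interaction the highest group mean counted and overlap was allowed. Up to 4 called members with the smallest p in the direction of each called list were added, and Mtr, Mthfd2, Mmut and Tcn2 among genes of folate and cobalamin metabolism in every comparison against control. The text names part of them. Some genes that the rule names are not reported here. Among the other observations, members of lists that were not called are named where their call held with any 1 library left out, or with the loss given. The genes and lists drawn in the plots were chosen after their values were seen. Plots were made with Python 3.11.15 and matplotlib 3.10.9.

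Comparisons that share libraries share chance values. Their correlation, covariance and overlaps were therefore set beside 100 simulated data sets with no effect and beside the overlap of independent lists. Genes were drawn independently in these simulations, and the mean over the data sets is given. Median-ratio scaling divided each library by its median ratio to the geometric mean of each gene. Other alternatives were quantile normalization, TPM without mitochondrially encoded genes, other pseudocounts and filters, no mean-variance trend, array weights, a block for the replicate number, a fit of only the groups compared, a fold threshold, and leaving out each library in turn. TPM without mitochondrially encoded genes and the ubiquitin loci Ubb-ps1 and Ubbl2 was added after these loci were seen to differ between libraries. Group labels were exchanged in all 10 splits of 3 against 3 libraries and in 100 regroupings of all libraries, the real one included (seed 1). Gene lengths came from a table of the assembly GRCr8, a different build from that of the values, and were used only as lengths.

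The code was tested on simulated data of 12263 genes in 10 runs. For MMA against control it recovered 51% of genes planted at a log2 fold of 0.3, 82.2% at 0.5, 98% at 1 and 99.2% at 2, with 10 false calls per run. For the interaction it recovered 16%, 60.8%, 93.4% and 97.4%, with 6.2 false calls per run. A G2/M list planted at 0.3 was called in 20 of 20 tests, and 0 of 720 other lists were. The genes of these simulations were drawn independently, so they cannot show how often correlated genes give false list calls. By the shares of planted genes recovered, changes at a log2 fold of 0.3 and also of 0.5 can be missed, most of all in the interaction. Fewer genes were planted in each run than were called in the data, which makes the adjusted threshold stricter. These shares need not hold for the real comparisons.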

Results

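RNA from H9c2 cells, a line from embryonic rat heart that the labels call cardiomyocytes, was measured by stranded sequencing of polyadenylated RNA. The 12 libraries fell into 4 groups of 3: control cells, cells given methylmalonic acid (MMA), cells given folic acid (FA), and cells given both (MMA+FA). MMA is an organic acid that builds up when the cobalamin-dependent breakdown of propionate is impaired. Folic acid is the synthetic form of folate. Doses and exposure times are not given in the sources used here. The labels do not say whether the replicates of a group were separate cultures, so the p-values below measure only the spread between these samples. The values were TPM, a length-scaled share of each library's total that keeps no depth, so the depth of each library is unknown. Of 30562 genes, 12263 had a mean of at least 1 TPM and were tested, and 10351 were listed at 0 in every library. Per library, 12276 ± 15.4 genes reached 1 TPM in the control group (SD, n = 3), 12193 ± 44.8 with MMA, 12221 ± 28.9 with FA and 12143 ± 64.9 with MMA+FA. Of the markers of other cell types, 2 of 12 endothelial, 3 of 14 leukocyte, 2 of 11 epithelial and 9 of 14 fibroblast and mesenchymal genes were abundant enough to be tested.

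The questions the design addresses are what MMA and FA each did to the transcriptome, what they did together, and whether the effect of one depended on the other. The first principal component held 25.4% of the variance of log2(TPM + 1). The control libraries lay at -16.1 ± 0.853 on it, the MMA libraries at -0.53 ± 5.99, the FA libraries at 0.12 ± 2.50 and the MMA+FA libraries at 16.5 ± 2.05 (mean ± SD, n = 3 each). The second component reached from -15.6 in MMA replicate 2 to 21.7 in FA replicate 3. Within groups, Pearson's r across genes lay between 0.987 and 0.990 for the FA libraries and between 0.990 and 0.992 for the other groups. Genes are not independent replicates, so these values describe likeness only. Across the 4 groups, 5031 genes differed in limma's F test at an adjusted p under 0.05, and 6485 at an unadjusted p under 0.05.

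**Figure D1:**
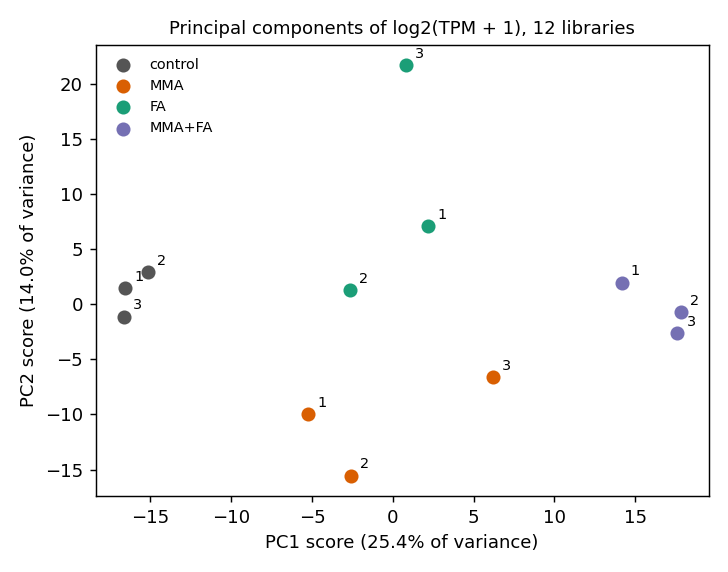
Scores of the 12 libraries on the first and second principal components of log2(TPM + 1), coloured by group and numbered by replicate. Control libraries lay between -16.7 and -15.1 on the first component and MMA+FA libraries between 14.2 and 17.8, with both single treatments in between.

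TPM is a share of a fixed total, so a gain in abundant transcripts lowers the values of the others. The 100 most abundant genes held 35.3 ± 0.295% of the total in control libraries, 36.9 ± 0.409% with MMA, 36.6 ± 0.0922% with FA and 37.8 ± 0.477% with MMA+FA (SD, n = 3). The median gene moved by -0.07 on the log2 scale with MMA, -0.05 with FA and -0.12 with MMA+FA, each against control. Mitochondrially encoded transcripts held 10.7 ± 0.49% of TPM in the libraries with MMA and 9.55 ± 0.56% in those without (SD, n = 6 each, exact permutation p = 0.00649). The most abundant ubiquitin locus, Ubb-ps1, held 2.83 ± 0.459% in control libraries and 3.62 ± 0.674% with FA (SD, n = 3), and it can share reads with near-identical copies, which was not examined, so its level is uncertain. Counts of higher and lower genes are therefore given for TPM as deposited and again after median-ratio scaling, which sets the typical gene to no change. All fold changes are on the log2(TPM + 1) scale, which understates changes of low genes.

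Compared to control, MMA alone raised Edn1, which encodes the precursor of endothelin-1, from 15.8 ± 3.17 to 32.2 ± 3.29 TPM (mean ± SD, n = 3 per group), a log2 fold change of 0.99 (SE 0.13, adjusted p = 0.00141 in limma). Tk1, the thymidine kinase of the cytosol, rose from 28.0 ± 3.41 to 49.5 ± 5.34 TPM (log2 0.80, SE 0.11, adjusted p = 0.00173), and the cold-inducible Rbm3 rose by 0.73 (SE 0.07, adjusted p = 0.000665). Frat2 rose by 0.99, Tnfsf18 by 0.81, the kinase gene Pim1 by 0.72, Il1rl1 by 0.66 and Tnfaip6 by 0.64, with adjusted p-values between 0.00101 and 0.00348. The immediate early gene Fosb fell from 117 ± 14.2 to 42.6 ± 25.5 TPM (log2 -1.63, SE 0.34, adjusted p = 0.00773). Its fellow stimulus-response genes Dusp5 (-0.81) and Zfp36 (-0.70) fell too. So did the chemokine gene Ccl2 (-0.79), the choline kinase gene Chka (-0.70), the homeobox gene Prrx2 (-0.68), the histone gene H4c14 (-1.15), Trpv2 (-0.71) and Pde4a (-0.66), with adjusted p-values from 5.62e-05 to 0.00903. Hes1 also fell (-0.93, adjusted p = 0.0129), a call lost without MMA replicate 3 (-0.70, adjusted p = 0.0557). The symbol Pclaf belongs to 2 loci that can share reads, so its size of change is uncertain. The locus annotated as a pseudogene (ENSRNOG00000016561) rose from 15.4 ± 7.44 to 64.1 ± 16.4 TPM (log2 2.06, SE 0.29, adjusted p = 0.00184) and the protein-coding one (ENSRNOG00000067723) from 42.6 ± 3.76 to 66.6 ± 9.28 TPM (log2 0.63, SE 0.146, adjusted p = 0.0123).

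MMA raised transcripts of DNA synthesis and mitosis. Rrm2 and Tyms, which supply deoxynucleotides, rose by 0.38 and 0.42, the primase gene Prim1 by 0.44, and the mitotic genes Ccnb2, Cdca8, Dlgap5 and Tpx2 by 0.37, 0.29, 0.27 and 0.26, with adjusted p-values between 0.00255 and 0.0074. Of 36 S phase genes, 14 were higher and 0 lower over all genes tested, and 21 and 0 adjusted over the list alone (median log2 0.23). Of 36 G2/M genes, 17 were higher and 0 lower, and 21 and 0 adjusted over the list alone (median 0.19). Under median-ratio scaling 19 and 26 were higher and 0 lower. Both lists ranked above other genes in limma's camera test at its preset correlation (adjusted p = 7.4e-16 each), and each had adjusted p = 0.323 with an estimated correlation. Transcripts of the mitochondrial genome that encode complex I subunits also rose, Mt-nd3 from 5633 ± 330 to 7996 ± 351 TPM (log2 0.51, SE 0.06), Mt-nd1 by 0.44, Mt-nd2 by 0.33 and Mt-nd4l by 0.30. Of 13 mitochondrially encoded genes, 6 were higher and 0 lower, the same counts adjusted over the list alone (median 0.25, adjusted p = 1.19e-08 at the preset and adjusted p = 0.323 with an estimated correlation).

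Lysosomal transcripts were lower with MMA. Npc1, which exports cholesterol from lysosomes, fell from 28.2 ± 0.525 to 19.6 ± 0.835 TPM (log2 -0.50, SE 0.06, adjusted p = 0.00087), and the protease gene Ctsl, the channel gene Mcoln1 and Lamp1 fell by 0.40, 0.37 and 0.22. Of 31 autophagy and lysosome genes, 0 were higher and 17 lower, and 0 and 19 adjusted over the list alone (median -0.16). Under median-ratio scaling 9 were lower (median -0.08). The list ranked below other genes at the preset correlation (adjusted p = 2.25e-05), and had adjusted p = 0.323 with an estimated correlation. Rrp12, Utp4 and Noc2l, which act in ribosome assembly, fell by 0.36, 0.23 and 0.22. Of 26 ribosome biogenesis genes, 9 were lower, 12 adjusted over the list alone (median -0.14), and 3 under median-ratio scaling (median -0.06; adjusted p = 0.00197 at the preset and adjusted p = 0.323 with an estimated correlation). The cholesterol gene Acat2 rose by 0.45, and 4 of 24 genes of that pathway were higher and 1 lower, also adjusted over the list alone, and 8 and 0 under median-ratio scaling, with a median of 0.19 (as deposited 0.12, adjusted p = 6.67e-05 at the preset and adjusted p = 0.428 with an estimated correlation). The cobalamin carrier gene Tcn2 fell by 0.26 (adjusted p = 0.0151), but not under median-ratio scaling (-0.18, adjusted p = 0.0716) or without control replicate 3 (-0.23, adjusted p = 0.0592). Mtr (-0.10), Mthfd2 (0.00) and Mmut (-0.26, adjusted p = 0.0614) did not pass.

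In all, limma called 2501 genes in MMA against control at an adjusted p under 0.05, 472 higher and 2029 lower (4415 at an unadjusted p under 0.05). Under median-ratio scaling the split was 1001 higher and 847 lower, and 472 higher and 847 lower were called under both scalings. The called changes were small, with a median size of 0.27, and 5 genes rose and 5 fell by at least 2-fold. The count was 1249 without control replicate 1, 1311 without control replicate 3 and 1173 without MMA replicate 3. Of 37 gene lists tested, 10 were called at the preset correlation, 8 up and 2 down, and 0 with an estimated correlation (17 by fry, which asks only whether a list moves one way). The remaining called lists were ribosomal proteins, the proteasome and histone genes (up, with medians of 0.03, 0.04 and 0.09), and extracellular matrix (up, median 0.05), whose call was lost without MMA replicate 3 (adjusted p = 0.15). Their median-ratio medians lay between 0.11 and 0.14. The 4 lists had adjusted p = 0.428, 0.323, 0.323 and 0.799 with an estimated correlation.

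Compared to control, FA alone raised Tnnt2 (ENSRNOG00000033734), which encodes cardiac troponin T, from 16.1 ± 2.41 to 44.5 ± 2.43 TPM (n = 3 per group; log2 1.42, SE 0.10, adjusted p = 4.81e-05). Prrx2 (ENSRNOG00000058329), a homeobox transcription factor of mesenchyme, fell from 36.0 ± 1.74 to 10.4 ± 1.15 TPM (log2 -1.70, SE 0.08, adjusted p = 5.17e-07). The signalling genes Smad9 and Wnt4 fell by 1.10 (SE 0.11) and 1.08 (SE 0.10), with adjusted p-values of 0.000554 and 0.000223. Cxcl1 fell from 82.4 ± 14.8 to 40.2 ± 4.21 TPM (log2 -1.01, SE 0.16, adjusted p = 0.00561), and Ccl2 by 0.94. Negr1 (-0.97), Samd11 (-0.97), Clec2g (-0.94), Car1 (-0.86), Nrn1 (-0.84) and the differentiation inhibitor Id2 (-0.77) fell as well, with adjusted p-values between 0.000118 and 0.00262. Edn1 rose from 15.8 ± 3.17 to 26.2 ± 1.85 TPM (log2 0.71, SE 0.13, adjusted p = 0.00954). Tmem204 (0.78), Nhsl1 (0.68), the elastic fibre gene Emilin1 (0.64) and Palmd (0.57) rose, with adjusted p-values between 0.0027 and 0.00554. Rpl15l3, a copy of a ribosomal protein gene whose reads can be hard to place, was 0.62 higher.

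Some contractile and matrix transcripts were higher with FA, though most members of these lists did not pass and single libraries decided several of the calls. Thbs1 rose by 0.26 (adjusted p = 0.0111). Col5a1 rose by 0.54 (adjusted p = 0.0126), a call lost without control replicate 3 (0.48, adjusted p = 0.0645) and without FA replicate 1 (0.50, adjusted p = 0.0535). Of 28 extracellular matrix genes, 9 were higher and 1 lower, and 11 and 1 adjusted over the list alone (median 0.20, adjusted p = 4.04e-07 at the preset and adjusted p = 0.532 with an estimated correlation). The smooth muscle actin gene Acta2 rose from 4302 ± 28.0 to 5260 ± 251.0 TPM (log2 0.29), a call lost without control replicate 3 (0.29, adjusted p = 0.056) and without FA replicate 1 (0.27, adjusted p = 0.0517). Of 14 smooth muscle genes 6 were higher and 0 lower, also adjusted over the list alone (median 0.14, adjusted p = 6.98e-06 at the preset and adjusted p = 0.421 with an estimated correlation). The skeletal actin gene Acta1 rose by 0.52 (adjusted p = 0.0146), again not without control replicate 3 (0.51, adjusted p = 0.0648) or FA replicate 1 (0.46, adjusted p = 0.0612). Of 18 skeletal muscle genes 5 were higher and 2 lower, and 7 and 3 adjusted over the list alone (median 0.22, adjusted p = 0.00356 at the preset and adjusted p = 0.421 with an estimated correlation).

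Some oxidant-response and iron transcripts were lower with FA, while the list of antioxidant enzymes was not called. Nqo1, a quinone reductase gene, fell from 216 ± 18.4 to 162 ± 10.6 TPM (log2 -0.41, SE 0.07, adjusted p = 0.00765) and the ferritin heavy chain gene Fth1 fell by 0.27 (SE 0.05, adjusted p = 0.0106). Of 23 targets of the oxidant-responsive factor NRF2, 9 were lower and 0 higher, 12 and 0 adjusted over the list alone, and 5 and 0 under median-ratio scaling (median -0.16, adjusted p = 0.00356 at the preset and adjusted p = 0.609 with an estimated correlation). Of 21 iron and ferroptosis genes, 7 were lower and 1 higher, and 12 and 4 adjusted over the list alone (median -0.15). That list was called at the preset correlation (adjusted p = 0.0403), with adjusted p = 0.421 with an estimated correlation, and lost its call under median-ratio scaling (adjusted p = 0.0615), with a replicate block (adjusted p = 0.0513), without control replicate 1 (adjusted p = 0.0552) and without FA replicate 1 (adjusted p = 0.0563). Cox5b fell by 0.22 (adjusted p = 0.0129). Nuclear genes of oxidative phosphorylation were lower in 7 of 48 cases and higher in 0, or 1 and 2 under median-ratio scaling (median -0.10, adjusted p = 0.0163 at the preset and adjusted p = 0.654 with an estimated correlation), and the call was lost under median-ratio scaling (adjusted p = 0.106) and without FA replicate 3 (adjusted p = 0.0998). Hmmr, a mitotic spindle gene, fell by 0.44 (adjusted p = 0.00619). Of 36 G2/M genes 4 were lower and 0 higher, 15 and 0 adjusted over the list alone, and 1 and 0 under median-ratio scaling, with a median of -0.07 (as deposited -0.12, adjusted p = 0.0145 at the preset and adjusted p = 0.703 with an estimated correlation), a list call lost without control replicate 2 (adjusted p = 0.0701) and FA replicate 2 (adjusted p = 0.0672). The S phase list had a median of 0.07, or 0.11 under median-ratio scaling, with the same adjusted p-values, lost without control replicate 3 (adjusted p = 0.0854) and FA replicate 1 (adjusted p = 0.165).

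With FA, genes of cholesterol synthesis and uptake ranked above other genes. Of 24 cholesterol genes 4 were higher and 1 lower, and 5 and 1 adjusted over the list alone (median 0.10, adjusted p = 0.00356 at the preset and adjusted p = 0.636 with an estimated correlation). Among the folate and cobalamin genes followed in each comparison, Mtr (0.01), Mthfd2 (0.03), Mmut (-0.20) and Tcn2 (-0.08) did not pass. limma called 1517 genes, 450 higher and 1067 lower (3809 at an unadjusted p under 0.05). Median-ratio scaling gave 709 higher and 476 lower, with 449 and 476 called under both scalings. By at least 2-fold, 5 genes rose and 10 fell. This count rested on single libraries: it was 621 without control replicate 1, 729 without control replicate 2, 214 without control replicate 3, 328 without FA replicate 1, 2571 without FA replicate 2 and 606 without FA replicate 3. Of the 53 genes named by the rule for this comparison, 24 kept their call in each of those fits. Of 37 lists, 9 were called, 5 up and 4 down, 0 with an estimated correlation and 15 by fry.

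Compared to control, both acids together raised Tnnt2 from 16.1 ± 2.41 to 73.6 ± 9.54 TPM (n = 3 per group; log2 2.12, SE 0.10, adjusted p = 2.63e-07), which is 2.24 relative to the shift of the typical gene of -0.12. Prrx2 fell from 36.0 ± 1.74 to 5.47 ± 0.475 TPM (log2 -2.52, SE 0.08, adjusted p = 4.49e-09, or -2.40 relative to the shift). Adjusted p-values of changes relative to the shift are those of median-ratio scaling in the next sentences. The muscle genes Lmod3 and Acta1 rose by 1.25 and 1.20 relative to the shift, the kinase gene Camk2a by 1.29, Myl4 by 0.95, Gmpr by 1.01 and Map3k7cl by 1.03, with adjusted p-values between 2.71e-05 and 7.52e-05. Edn1 rose by 1.19 relative to the shift, from 15.8 ± 3.17 to 34.2 ± 3.77 TPM (adjusted p = 8.74e-05). Wnt4 and Smad9 fell by 1.72 and 1.73 relative to the shift, Car1 by 1.67, Samd11 by 1.58, Negr1 by 1.35, Nrn1 by 1.13, Clec2g by 1.09 and Pde4a by 1.09, with adjusted p-values between 1.51e-06 and 6.03e-05. The chemokine gene Ccl7 fell by 1.43 relative to the shift (adjusted p = 0.00232), and the histone gene H4c14 by 1.24 (adjusted p = 0.000948). Cks2l1 was 1.27 lower before scaling (-1.27, adjusted p = 0.0421; without control replicate 3 -0.92, adjusted p = 0.164) and did not pass under median-ratio scaling (-1.15, adjusted p = 0.0718), so it is uncertain. The small nucleolar RNA Snord97 was listed at 0 in the 3 control libraries and at 36.6, 48.6 and 47.0 TPM with MMA+FA, but also at 0, 32.5 and 36.8 TPM with MMA and at 150, 0 and 0 TPM with FA.

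Cholesterol transcripts rose with both acids. Insig1 went from 13.4 ± 0.709 to 26.0 ± 3.80 TPM (log2 0.90, SE 0.10, adjusted p = 6.12e-05, or 1.02 relative to the shift), and Msmo1 rose by 0.55 relative to it. Of 24 genes of the pathway 13 were higher and 2 lower, and 15 and 2 adjusted over the list alone. Under median-ratio scaling 18 were higher and 0 lower (median 0.33, adjusted p = 1.32e-10 at the preset for TPM as deposited and adjusted p = 0.198 with an estimated correlation). Acta2, Tpm1, Tpm2 and Myl9 rose by 0.55, 0.37, 0.38 and 0.39 relative to the shift. Of 14 smooth muscle genes 7 were higher and 0 lower, 8 and 0 adjusted over the list alone, and 12 and 0 under median-ratio scaling (adjusted p = 3.4e-09 at the preset and adjusted p = 0.198 with an estimated correlation). The heart genes Casq2, Mef2c and Gata6 rose by 0.46, 0.52 and 0.43 relative to the shift. Of 16 cardiac genes 7 were higher and 3 lower, also adjusted over the list alone, and 8 and 1 under median-ratio scaling (adjusted p = 0.00206 at the preset and adjusted p = 0.198 with an estimated correlation). Of 18 skeletal muscle genes 7 were higher and 3 lower, and 8 and 3 adjusted over the list alone, a list call that median-ratio scaling ended (adjusted p = 0.00702 at the preset, 0.157 with that scaling and adjusted p = 0.418 with an estimated correlation). Mt-nd3, Mt-nd1, Mt-nd4l and Mt-nd2 rose by 0.63, 0.50, 0.48 and 0.41 relative to the shift, and of 13 mitochondrially encoded genes 6 were higher and 0 lower, 7 and 0 adjusted over the list alone, and 9 and 0 under median-ratio scaling (adjusted p = 8.34e-08 at the preset and adjusted p = 0.418 with an estimated correlation).

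Mitotic and oxidant-response transcripts fell with both acids. Hmmr fell from 48.6 ± 1.77 to 29.2 ± 1.40 TPM (log2 -0.72, SE 0.07, adjusted p = 4.55e-05), and Hmmr, Nusap1, Bub1b and Cdk1 fell by 0.60, 0.43, 0.30 and 0.26 relative to the shift. Of 36 G2/M genes 0 were higher and 27 lower, and 0 and 29 adjusted over the list alone. Under median-ratio scaling 1 was higher and 19 lower (median -0.16; for TPM as deposited the median was -0.29, adjusted p = 2.87e-06 at the preset and adjusted p = 0.428 with an estimated correlation). Tk1 and Mcm6 rose by 0.75 and 0.76 relative to the shift, and of 36 S phase genes 7 were higher and 4 lower, also adjusted over the list alone, and 13 and 1 under median-ratio scaling (adjusted p = 0.00081 at the preset and adjusted p = 0.552 with an estimated correlation). The haem oxygenase gene Hmox1 fell from 305 ± 18.4 to 193 ± 20.7 TPM (log2 -0.66, SE 0.07, adjusted p = 6.28e-05), or by 0.54 relative to the shift, and Ftl1 and Gclc fell by 0.37 and 0.33. Of 23 NRF2 targets 1 was higher and 15 lower, 2 and 15 adjusted over the list alone, and 3 and 11 under median-ratio scaling (adjusted p = 0.00834 at the preset and adjusted p = 0.428 with an estimated correlation). Psmd3 and Psmb1 rose by 0.46 and 0.34 relative to the shift, and Rpl15 by 0.55. Proteasome and ribosomal protein lists were called up, with median-ratio medians of 0.20 and 0.15 (adjusted p = 0.198 and adjusted p = 0.426 with an estimated correlation). Nuclear genes of oxidative phosphorylation were called up although their median (-0.03) and mean (-0.06) lay below 0. Their median-ratio median was 0.10, the call was lost without MMA+FA replicate 2 (adjusted p = 0.0547), and the list had adjusted p = 0.428 with an estimated correlation.

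Against control, limma called 4818 genes with MMA+FA, 818 higher and 4000 lower (5954 at an unadjusted p under 0.05). Median-ratio scaling gave 1898 higher and 1710 lower, and 818 and 1710 were called under both scalings. By at least 2-fold, 11 genes rose and 42 fell. The count stayed between 3605 and 4106 when any 1 library of those groups was left out, and 59 of the 64 genes named by the rule kept their call in each of those fits. Mtr was 0.23 lower before scaling (-0.23, adjusted p = 0.0023) and did not pass under median-ratio scaling (-0.11, adjusted p = 0.0601). Mthfd2 (-0.12), Mmut (-0.19) and Tcn2 (-0.15) did not pass. Of 37 lists 11 were called, 9 up and 2 down, 0 with an estimated correlation, 24 by fry and 14 under median-ratio scaling.

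**Figure D2:**
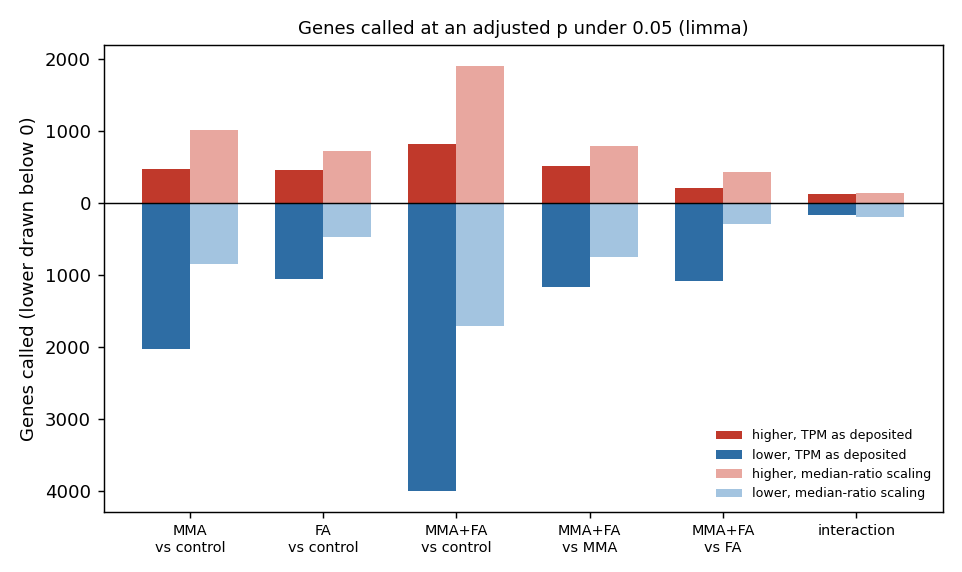
Genes called at an adjusted p under 0.05 in each comparison (limma), higher above 0 and lower below 0, for TPM as deposited and after median-ratio scaling. For MMA+FA against control the split was 818 higher and 4000 lower as deposited and 1898 higher and 1710 lower after scaling.

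Adding FA to MMA was asked by comparing MMA+FA with MMA alone. Tnnt2 rose from 21.4 ± 1.55 to 73.6 ± 9.54 TPM (n = 3 per group; log2 1.73, SE 0.10, adjusted p = 4.58e-06). Acta1 rose from 3.05 ± 0.459 to 9.25 ± 1.25 TPM (log2 1.34, SE 0.11, adjusted p = 2.76e-05). The muscle genes Lmod3 (0.84), Tnnc2 (0.72) and Trim63 (0.72, a ubiquitin ligase of muscle), the endothelin receptor gene Ednra (0.69), Lbh (0.71), Slit3 (0.71) and Gmpr (0.70) rose, with adjusted p-values between 5.07e-05 and 0.00106. Prrx2 fell from 22.04 ± 1.32 to 5.47 ± 0.475 TPM (log2 -1.83, SE 0.08, adjusted p = 2.09e-07) and Wnt4 from 12.9 ± 1.37 to 3.76 ± 0.411 TPM (log2 -1.55, SE 0.10, adjusted p = 7.04e-06). Car1 (-1.36), Smad9 (-1.23), Samd11 (-1.22), Ifitm10 (-1.15), Cd200 (-1.03), Negr1 (-0.92) and the myogenic factor Myod1 (-0.90) fell, with adjusted p-values between 1.77e-05 and 0.000643. Adgrg1 fell by 1.09 (adjusted p = 0.00338). The Pclaf loci fell by 1.32 and 0.49 (adjusted p = 0.0106 and 0.0453), with the uncertainty given above. Hmgn1l1, a copy of another gene and so uncertain, was 0.74 higher, a call lost without MMA replicate 1 (0.69, adjusted p = 0.0564). The small RNA Scarna6l was listed at 0 in the 3 MMA+FA libraries and at 6.70, 6.35 and 7.58 TPM with MMA, while the control libraries had 0, 0 and 3.30 TPM and the FA libraries 10.5, 0 and 0 TPM.

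Mitotic transcripts fell when FA was added to MMA. Cdk1 fell from 164 ± 3.91 to 111 ± 6.64 TPM (log2 -0.56, SE 0.05, adjusted p = 3.48e-05), Nusap1 by 0.65, Dlgap5 by 0.56 and Prc1 by 0.50. Of 36 G2/M genes 0 were higher and 34 lower, also adjusted over the list alone (median -0.51, adjusted p = 4.38e-29 at the preset and adjusted p = 0.122 with an estimated correlation). Rrm2, Rrm1, Rfc4 and Ccne1 fell by 0.55, 0.33, 0.35 and 0.29. Of 36 S phase genes 9 were lower, 13 adjusted over the list alone (median -0.17, adjusted p = 0.00154 at the preset and adjusted p = 0.657 with an estimated correlation), a call lost without MMA replicate 3 (adjusted p = 0.0975) and without MMA+FA replicate 1 (adjusted p = 0.0767). The smooth muscle genes Lmod1, Myl9, Tpm2 and Tpm1 rose by 0.43, 0.33, 0.30 and 0.28, and 9 of 14 such genes were higher and 0 lower, also adjusted over the list alone (median 0.26, adjusted p = 1.78e-11 at the preset and adjusted p = 0.122 with an estimated correlation). Casq2 and Mef2c rose by 0.24 and 0.37, and 3 of 16 cardiac genes were higher and 2 lower, 4 and 2 adjusted over the list alone (median 0.11, adjusted p = 0.00154 at the preset and adjusted p = 0.122 with an estimated correlation). Insig1, Msmo1 and Lss rose by 0.68, 0.41 and 0.36, and 5 of 24 cholesterol genes were higher and 0 lower, also adjusted over the list alone (adjusted p = 1.42e-05 at the preset and adjusted p = 0.402 with an estimated correlation).

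Some transcripts that MMA alone had moved went the other way when FA was present. Egr1, Ier2, Btg2 and Dusp5 rose by 0.55, 0.47, 0.48 and 0.52 over MMA alone, and 10 of 27 immediate early genes were higher and 3 lower, 11 and 3 adjusted over the list alone (median 0.12, adjusted p = 7.76e-05 at the preset and adjusted p = 0.402 with an estimated correlation). The lysosomal genes Atp6v0d1 (from 117 ± 1.06 to 151 ± 6.87 TPM, log2 0.35, SE 0.04, adjusted p = 0.00018), Hexa (0.24), Map1lc3a (0.23) and Lamp1 (0.20) rose. Of 31 autophagy and lysosome genes 11 were higher and 1 lower, 12 and 4 adjusted over the list alone (median 0.07, or 0.11 under median-ratio scaling, adjusted p = 6.1e-05 at the preset and adjusted p = 0.402 with an estimated correlation). These comparisons share the MMA libraries, so chance alone gives opposite signs: across genes the covariance of the 2 changes was -0.0117 (r -0.239), and -0.00924 (r -0.505) in simulated groups with no effect. The NRF2, NF-kB and interferon lists did not go the other way. Their mean log2 levels were 6.57, 4.49 and 3.81 in control libraries. With MMA they were 6.49, 4.30 and 3.72, and with MMA+FA 6.28, 4.08 and 3.56. Nqo1, Osgin1 and Ftl1 fell by 0.43, 0.62 and 0.31 from MMA to MMA+FA, and 8 of 23 NRF2 targets were lower, 13 adjusted over the list alone (median -0.19, adjusted p = 0.000391 at the preset and adjusted p = 0.402 with an estimated correlation). Nfkbia, Csf1 and Il6 fell by 0.60, 0.51 and 0.41, and Gbp2 by 0.34. The NF-kB list (median -0.22) and the interferon list (median -0.13) were called down at the preset correlation, with adjusted p = 0.534 and adjusted p = 0.402 with an estimated correlation. Both calls were lost without MMA replicate 3 (adjusted p = 0.06 each) and MMA+FA replicate 1 (adjusted p = 0.0824 and 0.0967), and the first also without MMA replicate 1 (adjusted p = 0.074) and MMA+FA replicate 3 (adjusted p = 0.156). Pfkm rose by 0.35. Glycolysis (median 0.08, or 0.12 under median-ratio scaling) and proteasome (median 0.03, or 0.07) were called up, had adjusted p = 0.474 and adjusted p = 0.534 with an estimated correlation, and lost their calls without MMA replicate 1 (adjusted p = 0.0502 and 0.0778) and MMA replicate 2 (adjusted p = 0.0581 and 0.072), the second also without MMA+FA replicate 3 (adjusted p = 0.0644).

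In MMA+FA against MMA, limma called 1683 genes, 514 higher and 1169 lower (3462 at an unadjusted p under 0.05). Under median-ratio scaling there were 784 higher and 759 lower, and 514 and 759 were called under both scalings. By at least 2-fold, 5 genes rose and 14 fell. The count was 869 without MMA replicate 1 and 868 without MMA replicate 2. Of 67 genes named by the rule, 55 kept their call whichever library of those groups was left out. Of 37 lists 12 were called, 7 up and 5 down, 0 with an estimated correlation and 14 by fry.

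Adding MMA to FA was asked by comparing MMA+FA with FA alone. Tnnt2 rose from 44.5 ± 2.43 to 73.6 ± 9.54 TPM (n = 3 per group; log2 0.71, SE 0.10, adjusted p = 0.00406), Prrx2 fell from 10.4 ± 1.15 to 5.47 ± 0.475 TPM (log2 -0.82, SE 0.08, adjusted p = 0.00134), and the transcription factor gene Cebpd fell from 12.6 ± 0.367 to 7.66 ± 0.165 TPM (log2 -0.65, SE 0.05, adjusted p = 0.000525). These 3 were the only ones of 57 genes named by the rule whose call held in every setting. The following ones were called in the fit of all 12 libraries and in each fit that left out 1 library, but not when only the FA and MMA+FA libraries were fitted. The cholesterol regulator Insig1 rose from 15.3 ± 1.09 to 26.0 ± 3.80 TPM (log2 0.72, SE 0.10, adjusted p = 0.00264), or adjusted p = 0.0511 with only those groups. Acta1 rose by 0.58 and the caveolar gene Cavin4 by 0.49. Myod1 fell from 55.2 ± 8.33 to 31.7 ± 3.30 TPM (log2 -0.77, SE 0.10, adjusted p = 0.00207), Wnt4 by 0.75, Inhbe by 0.70, Kcnh1 by 0.69, Gse1 by 0.69, Atoh8 by 0.67 and Mex3b by 0.63. Mt-nd5, Mt-nd4l, Mt-nd1 and Mt-nd2 rose by 0.42, 0.38, 0.38 and 0.35, the nuclear complex I gene Ndufa3 by 0.29, and the antioxidant genes Mgst3 and Gpx1 by 0.45 and 0.18. The collagen genes Col11a1 and Col5a2 fell by 0.48 and 0.28, the mitotic genes Nusap1, Bub1b and Cdk1 by 0.38, 0.26 and 0.25, and the tRNA synthetase gene Eprs1 by 0.26. Rpl36l5 and Hmgn1l1, copies whose reads can be hard to place, were 2.02 and 0.69 higher and are uncertain. Their calls were lost without FA replicate 3 (Rpl36l5 1.74, adjusted p = 0.112) and without MMA+FA replicate 2 (Hmgn1l1 0.69, adjusted p = 0.0796).

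Of 13 mitochondrially encoded genes 7 were higher and 0 lower with MMA+FA than with FA, 8 and 0 adjusted over the list alone (median 0.26, adjusted p = 3.63e-13 at the preset and adjusted p = 0.189 with an estimated correlation). Of 48 nuclear oxidative phosphorylation genes 7 were higher and 0 lower, 10 and 0 adjusted over the list alone, and 12 and 0 under median-ratio scaling, with a median of 0.16 (as deposited 0.09, adjusted p = 3.63e-13 at the preset and adjusted p = 0.146 with an estimated correlation). Mean log2 levels of that list overlapped between libraries, at 7.23, 7.41 and 7.32 with FA and 7.34, 7.46 and 7.33 with MMA+FA. Cholesterol genes were higher in 5 of 24 cases and lower in 0, 6 and 0 adjusted over the list alone (median 0.18, adjusted p = 6.94e-11 at the preset and adjusted p = 0.165 with an estimated correlation). Of 36 G2/M genes 15 were lower, 22 adjusted over the list alone, and 5 under median-ratio scaling, with a median of -0.11 (as deposited -0.19, adjusted p = 9.54e-07 at the preset and adjusted p = 0.43 with an estimated correlation). Of 28 extracellular matrix genes 8 were lower, 15 adjusted over the list alone, and 3 under median-ratio scaling, with a median of -0.13 (as deposited -0.20, adjusted p = 0.000197 at the preset and adjusted p = 0.46 with an estimated correlation). Of 34 stress-response targets of ATF4 10 were lower and 1 higher, 19 and 1 adjusted over the list alone, and 1 and 1 under median-ratio scaling (median -0.16, adjusted p = 0.000835 at the preset and adjusted p = 0.469 with an estimated correlation). Proteasome, ribosomal protein, smooth muscle, cardiac and endoplasmic reticulum chaperone lists were called up with medians between 0.01 and 0.07, or 0.09 and 0.15 under median-ratio scaling (adjusted p = 0.146, 0.341, 0.348, 0.146 and 0.146 with an estimated correlation), and the cardiac one not without FA replicate 2 (adjusted p = 0.0507). The antioxidant enzyme list was called up although its median was -0.01, or 0.07 under median-ratio scaling, and its mean 0.03 (adjusted p = 0.0118 at the preset and adjusted p = 0.34 with an estimated correlation).

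In MMA+FA against FA, limma called 1288 genes, 196 higher and 1092 lower (3594 at an unadjusted p under 0.05). Median-ratio scaling gave 421 higher and 302 lower, 195 and 302 under both scalings. By at least 2-fold, 5 genes rose and 5 fell. This count depended on the fit: 23 genes were called when only those 6 libraries were fitted, 357 without FA replicate 1, 2010 without FA replicate 2, 505 without FA replicate 3, 362 without MMA+FA replicate 2 and 431 without MMA+FA replicate 3. Of 37 lists 12 were called, 9 up and 3 down, 0 with an estimated correlation and 17 by fry.

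**Figure D3:**
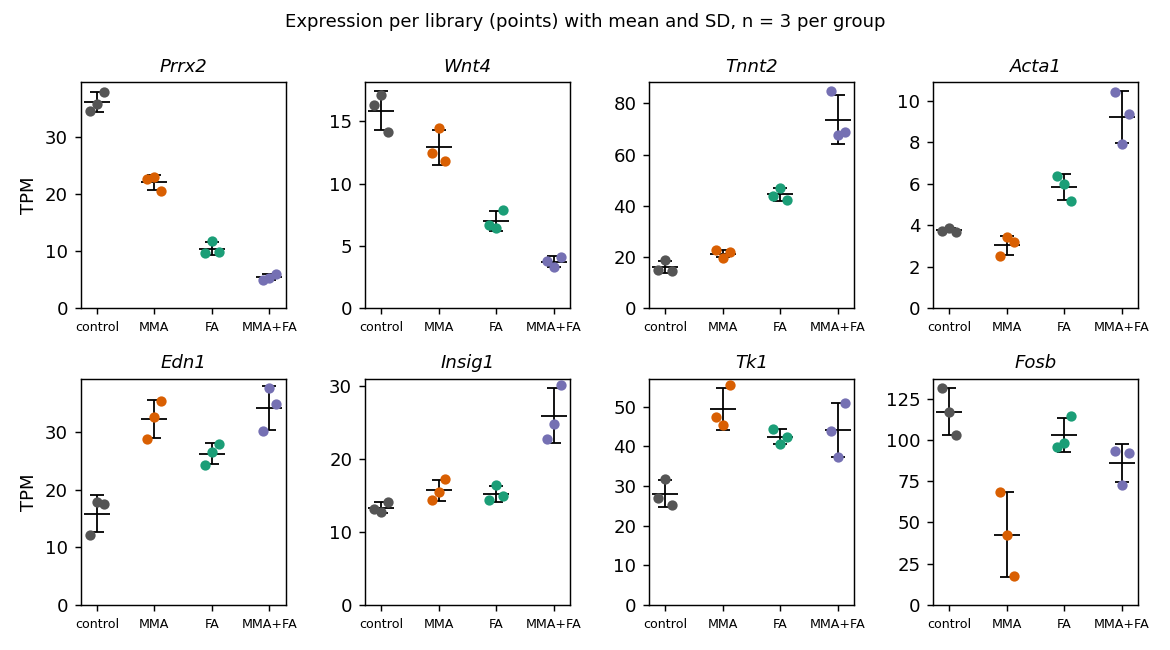
TPM per library (points) with group mean and SD (n = 3) for 8 genes chosen after their values were seen. Prrx2 and Wnt4 were lowest and Tnnt2 and Acta1 highest with MMA+FA, while Fosb was lowest with MMA alone (42.6 ± 25.5 TPM against 86.1 ± 11.4 TPM with MMA+FA).

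Whether the MMA effect depended on FA was tested as the interaction, which is the difference MMA+FA minus FA, less the difference MMA minus control. Palmd was raised by MMA alone (from 11.3 ± 0.904 to 17.2 ± 0.353 TPM) and lowered by MMA on top of FA (from 17.2 ± 1.00 to 12.02 ± 1.14 TPM), an interaction of -1.05 (n = 3 per group, SE 0.10, adjusted p = 0.00331). Sapcd1 (-0.83, adjusted p = 0.00849), Pimreg (-0.78, adjusted p = 0.0112), Il1rl1 (-0.84, adjusted p = 0.0146) and the linker histone genes H1f10 (-0.95, adjusted p = 0.0146) and H1f0 (-0.54, adjusted p = 0.00927) had negative interactions as well. The mitotic genes Aurkb (-0.51), Dlgap5 (-0.49), Tpx2 (-0.49) and Cdk1 (-0.43) did so with adjusted p-values between 0.0112 and 0.0146. In the other direction, the proton pump gene Atp6v0b fell with MMA alone (from 110 ± 4.85 to 79.3 ± 3.04 TPM) and was at 95.6 ± 5.37 TPM with MMA+FA against 85.6 ± 2.89 TPM with FA, an interaction of 0.62 (SE 0.07, adjusted p = 0.00849). Lyset (0.75), Dok5 (0.74), Renbp (0.57), Trim63 (0.55), Mfsd11 (0.53), Npc1 (0.53), Atp6v0d1 (0.32) and Lamp1 (0.31) had positive interactions, with adjusted p-values between 0.00849 and 0.0147. The pseudogene locus of Pclaf had -2.44 (SE 0.41, adjusted p = 0.0146) and the protein-coding locus -0.69 (SE 0.206, adjusted p = 0.106), which did not pass, so Pclaf stays uncertain. Ndufv3-ps1 (0.97, adjusted p = 0.0485; without FA replicate 1 0.90, adjusted p = 0.123) is a pseudogene copy and equally uncertain. Acta1 had an interaction of 0.82 (adjusted p = 0.0205), which did not pass without control replicate 1 (0.82, adjusted p = 0.0576) or control replicate 3 (0.83, adjusted p = 0.0515).

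Of 36 G2/M genes, 18 had a negative and 0 a positive interaction, 31 and 0 adjusted over the list alone (median -0.38, adjusted p = 5.47e-26 at the preset and adjusted p = 0.295 with an estimated correlation). The mean level of that list on the log2 scale was 5.68 ± 0.0485 in control libraries, 5.85 ± 0.0114 with MMA, 5.56 ± 0.0354 with FA and 5.36 ± 0.0938 with MMA+FA (SD, n = 3). Of 31 autophagy and lysosome genes, 8 had a positive and 0 a negative interaction, 13 and 0 adjusted over the list alone (median 0.15, adjusted p = 3.59e-08 at the preset and adjusted p = 0.295 with an estimated correlation). The S phase (median -0.23), extracellular matrix (median -0.19) and histone (median -0.22) lists were called down, with 3, 2 and 2 members past the threshold, and had adjusted p = 0.526, 0.4 and 0.295 with an estimated correlation. Nuclear oxidative phosphorylation (median 0.09), smooth muscle (median 0.07) and ribosome biogenesis (median 0.07) were called up with 0 members past the threshold, and had adjusted p = 0.526, 0.684 and 0.358 with an estimated correlation. The smooth muscle call was lost without FA replicate 2 (adjusted p = 0.0967) and MMA replicate 2 (adjusted p = 0.0946), and the ribosome biogenesis call without FA replicate 2 (adjusted p = 0.0737) and MMA+FA replicate 2 (adjusted p = 0.0906).

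limma called 295 genes for the interaction, 115 positive and 180 negative (2163 at an unadjusted p under 0.05), and 127 and 199 under median-ratio scaling. The count ranged widely with single libraries: without control replicates 1, 2 and 3 it was 85, 182 and 96, without FA replicates 1 and 2 it was 92 and 496, without MMA replicates 1, 2 and 3 it was 154, 132 and 109, and without MMA+FA replicates 1 and 2 it was 177 and 125. Of 37 genes named by the rule and called, 21 kept their call in each fit that left out 1 library, and the others reached adjusted p-values between 0.0512 and 0.126 in at least 1 such fit. Of the 4818 genes called in MMA+FA against control, 154 (3.2%) were among the 295. All 193 of the 295 that MMA alone had also changed had an interaction opposite in sign to that change, as did 95 of the 108 that FA alone had changed. The control libraries and the single-treatment libraries enter both values with opposite signs, so chance favours such a result. Of 37 lists 8 were called, 4 up and 4 down, 0 with an estimated correlation and 5 by fry.

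**Figure D4:**
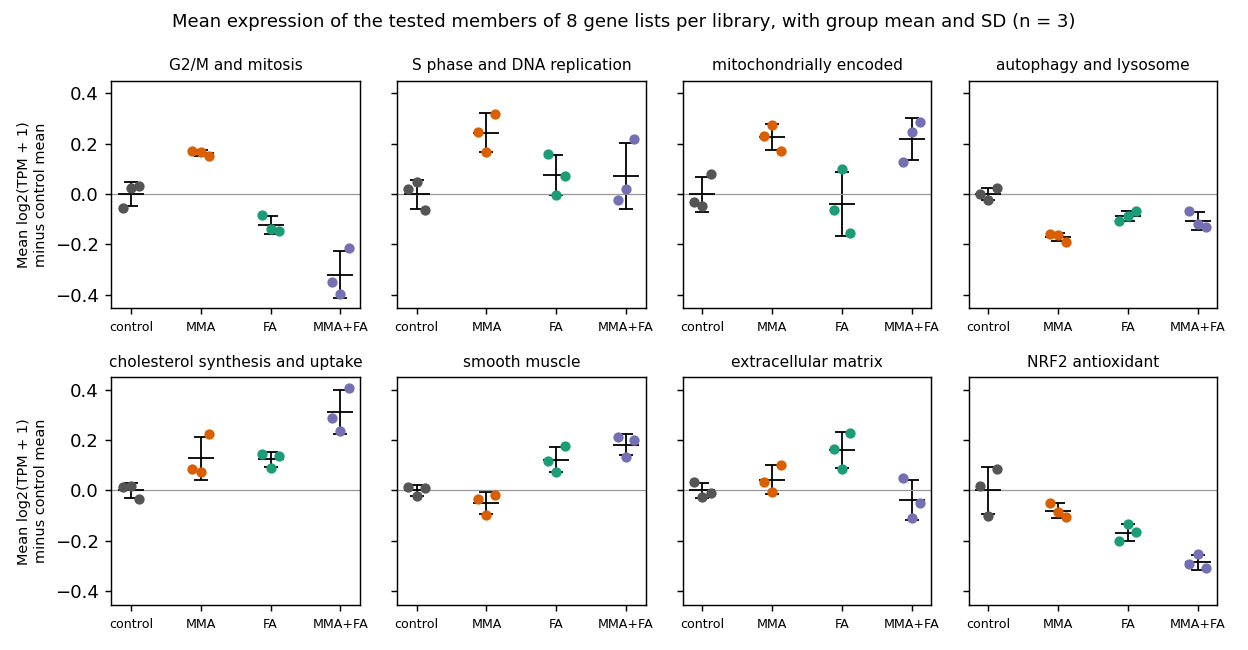
Mean log2(TPM + 1) of the tested members of 8 gene lists in each library, minus the control mean, with group mean and SD (n = 3); the lists were chosen after their values were seen. The G2/M list averaged 5.85 with MMA alone and 5.36 with MMA+FA, against 5.68 in control libraries.

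The MMA effect without FA (MMA minus control) and with FA (MMA+FA minus FA) share no library. Of the 2501 genes called with MMA alone, 80.97% had the same sign in the presence of FA, and 74.4% of the 1848 called under median-ratio scaling. Of all tested genes, 66.43% had the same sign. Across genes, which are not independent replicates, r was 0.225 with a covariance of 0.0102. Groups simulated with no effect gave a mean covariance of -9.57e-05. Their genes were independent, so this does not show the spread that correlated genes give. As high an r came up in 11 of 100 regroupings of the libraries, so it is not beyond a random grouping by that test. Among called genes 27 were higher and 440 lower in both and 36 opposite, where independent lists would share 7.54, 180.7 and 74.5. Under median-ratio scaling 113 were higher, 85 lower and 28 opposite, where independent lists would share 34.4, 20.9 and 53.7. For the FA effect without and with MMA, 81.41% of 1517 genes had the same sign (81.6% of 1185 under median-ratio scaling), r was 0.273 and the covariance 0.0133 (simulated -0.000193), and 118 genes were higher, 300 lower and 34 opposite in both (independent lists 18.9, 101.7 and 87.6). Of all tested genes 65.09% had the same sign, and as high an r came up in 2 of 100 regroupings. Median-ratio scaling gave 218 genes higher, 136 lower and 20 opposite for the FA effects (independent lists 45.3, 29.5 and 74.3). For both pairs of effects the main direction of the shared changes depends on the scaling.

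MMA alone and FA alone were compared against the same control libraries, so their likeness holds a part from chance. Among genes called in both, 148 were higher in both, 588 lower in both and 7 opposite, where independent lists would share 17.3, 176.5 and 115.5. Under median-ratio scaling 318 were higher, 192 lower and 3 opposite, where independent lists would share 57.9, 32.9 and 87.8. The main direction of the shared changes therefore depends on the scaling. Across genes r was 0.541, and 0.501 in simulated groups with no effect that shared the controls. The covariance was 0.0250 against a simulated 0.0092, a difference of 0.0158. With 1 control library given to one effect and the other 2 to the other, an addition made after the data were seen, the covariance was 0.0127 to 0.0159 in the 6 possible ways. With 3 control libraries no split leaves 2 on each side, so the counts of shared genes were not split, and part of their excess may come from the controls. Edn1 rose with each acid alone (0.99 with MMA and 0.71 with FA), while Prrx2 (-0.68 and -1.70) and Ccl2 (-0.79 and -0.94) fell with each.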

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

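Of the tests in this part, those of the 100 most abundant genes, of scaling for the G2/M list, of the mitochondrial ratio and of gene length per library were chosen after the result was seen, as were the regroupings of single lists other than G2/M. The regrouping of the G2/M list was added later than the other tests of that list, but before any regrouping of it was computed. The remaining tests were chosen before. The genes and lists of this paragraph were picked out because the interaction test found that the effect of MMA differed between cells without and with FA. It picked out 295 genes. The lists it picked out were nuclear oxidative phosphorylation (median 0.093), S phase (-0.23), G2/M (-0.381), extracellular matrix (-0.192), smooth muscle (0.0714), autophagy and lysosome (0.149), ribosome biogenesis (0.0741) and histone genes (-0.221). The largest positive genes were Ndufv3-ps1 (0.97), Acta1 (0.82), Lyset (0.75), Dok5 (0.74), Atp6v0b (0.62), Fnip1 (0.58), Mat1a (0.57), Trnp1 (0.57), Renbp (0.57), Trim63 (0.55), Mfsd11 (0.53) and Npc1 (0.53). The largest negative ones were Pclaf (-2.44), Palmd (-1.05), H1f10 (-0.95), Il1rl1 (-0.84), Sapcd1 (-0.83), Pimreg (-0.78), Tk1 (-0.76), Htatip2 (-0.75), Csrp2 (-0.75), Vgf (-0.74), Sema6c (-0.72) and E2f2 (-0.69). Not all of these calls held when 1 library was left out. The highest adjusted p-values reached were 0.123 for Ndufv3-ps1, 0.108 for Trnp1, 0.0896 for E2f2, 0.0864 for Htatip2, 0.0799 for Tk1, 0.0774 for Sema6c, 0.0692 for Vgf, 0.0671 for Mat1a, 0.0658 for Csrp2, 0.0618 for Fnip1 and 0.0576 for Acta1.

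In 100 regroupings of the libraries, the real one included, 1 called as many genes in the F test as the real grouping (5031, highest other 437). A random grouping does not account for that count. For the interaction, 1 of 100 called as many genes (295, highest other 234). That cannot decide on the interaction count, since differences between the real groups widen the spread within regroupings and so lower their counts. As many interaction lists (8, highest other 14) came up in 54 of 100, so a random grouping is not excluded for their number. Of single lists, as large a median came up in 11 of 100 for nuclear oxidative phosphorylation, 13 for S phase, 11 for extracellular matrix, 54 for smooth muscle, 3 for lysosome, 39 for ribosome biogenesis and 4 for histone genes. A correlation of the MMA effects as high as the real one (0.225, highest other 0.458) came up in 11 of 100, and for the FA effects (0.273, highest other 0.347) in 2 of 100. The first is not beyond a random grouping by this test and the second is. Regroupings mix libraries of different groups, so real differences between groups also enter their values.

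Exchanging labels among 6 libraries gives 10 splits, too few for a share under 0.05. The real split called the most genes in MMA against control (1 of 10 splits; 2501, highest other 1), FA against control (1; 1517, highest other 0), MMA+FA against control (1; 4818, highest other 0), MMA+FA against MMA (1; 1683, highest other 0) and MMA+FA against FA (1; 1288, highest other 1). For lists, 3 of 10 splits called as many in MMA against control (10, highest other 10), 4 in FA against control (9, highest other 10), 3 in MMA+FA against control (11, highest other 12), 1 in MMA+FA against MMA (12, highest other 10) and 1 in MMA+FA against FA (12, highest other 10). Numbers of called lists at the preset correlation are therefore weak evidence in this series.

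G2/M genes were higher with MMA alone and lower when FA was added. A single library does not account for this, since the median interaction reached at most -0.345 when 1 library was left out. TPM scaling does not either, since a factor per library cancels in the log2 ratio of the list to all other genes within a library, and that ratio had an interaction of -0.365 (SE 0.0579). As large a median (-0.381, highest other 0.611) came up in 8 of 100 regroupings, so a random grouping is not excluded. The biological reading, an effect of FA on mitotic transcripts in the presence of MMA, was compared only through the group labels.

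For the excess of lower over higher genes in MMA+FA against control, without the 100 most abundant genes and with the rest rescaled, the median gene lay at -0.068 (-0.072 to -0.058 with 1 library left out), against -0.12 for all genes, and 2755 of 3933 called genes (70.05%) were lower. The criterion for reading this value was changed after the value was seen: the first bound of -0.06 would have counted against the explanation, and the value was then called open because its leave-one-out range crosses that bound. The change correlated with gene length (rho -0.182 across genes, which are not independent replicates), which leaves a length trend open, with lengths matched for 11263 of 12263 genes. The rho was -0.203 in MMA against control, -0.0827 in FA against control and -0.175 in MMA+FA against FA. The tests of gene lists took no account of gene length. The median log2 deviation of the longest genes minus that of the shortest was -0.0436 ± 0.029 in libraries with MMA and 0.0396 ± 0.0231 without (n = 6 each, exact permutation p = 0.00216). Composition, length and a wider biological decrease cannot be told apart here.

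Mitochondrially encoded transcripts were higher in the libraries with MMA. The log2 ratio of the Mt-nd transcripts to the other mitochondrial ones within a library was -2.35 ± 0.07 with MMA and -2.57 ± 0.04 without (SD, n = 6 each, exact permutation p = 0.00216, the smallest possible). The split into Mt-nd and other transcripts was chosen after the result was seen, which favours a difference. The p-value therefore does not by itself exclude an equal gain of all of them. No scaling can change a ratio within a library, and the lowest library with MMA lay 0.0783 above the highest without. The Mt-nd transcripts had a median of 0.30 and the others 0.09 in MMA against control, and 0.38 and 0.13 in MMA+FA against FA. The capture of mitochondrial transcripts by polyA selection was not tested.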

How the results depend on the processing

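Under median-ratio scaling the excess of lower over higher genes turned into an excess of higher ones for FA (709 and 476), MMA (1001 and 847), MMA+FA against control (1898 and 1710), against FA (421 and 302) and against MMA (784 and 759). Genes called (FA, MMA and MMA+FA against control, MMA+FA against FA, MMA+FA against MMA, interaction) at a log2 fold change of at least 1 were 15, 10, 53, 10, 19 and 4, fewer by construction. With array weights 3577, 3858, 2279, 2876 and 954 were called (no large move for MMA+FA against control). The default estimate of these weights did not converge, so after its counts had been seen it was replaced by the gene-by-gene estimate used here. Without a filter FA, MMA+FA against FA and the interaction had 928, 699 and 181, where more genes are tested. With only the groups compared, FA had 604 and MMA+FA against FA 23, where fewer libraries set the spread. MMA+FA against FA had 723 under median-ratio scaling and 507 under quantile normalization. The same-sign share was 84.8% for FA among the genes with the smallest p, and for MMA 77.58% without mitochondrially encoded genes, 74.4% under median-ratio scaling and 71.49% under quantile normalization. With an estimated correlation, lists called were 0, 0, 0, 0, 0 and 0 in those comparisons, and fry called 15 for FA, 17 for MMA, 24 for MMA+FA against control and 5 for the interaction. Under median-ratio scaling, added later, fry called 4, 14, 22 and 3. Where no construction is named, the cause was not tested.

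With 1 library left out, genes called ranged from 214 to 2571 for FA, 1173 to 1898 for MMA, 3605 to 4106 for MMA+FA against control, 357 to 2010 against FA, 868 to 1696 against MMA, 85 to 496 for the interaction and 3518 to 6292 in the F test. Lists ranged from 8 to 14, 9 to 11, 11 to 15, 12 to 15, 9 to 12 and 6 to 9. Same-sign shares ranged from 78.4% to 87.01% for FA and 77.05% to 82.35% for MMA. Each named gene was counted once per comparison and setting, also where it was not called. By that count 2256 results stayed on their side of the threshold, 17 became stronger and 403 weaker when 1 library was left out, and 4308, 76 and 215 under other settings. For called lists, counted once per comparison and setting, 393 results stayed and 27 became weaker with 1 library left out, and 220 and 90 under other settings.

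With the replicate number as a block (replicate block), 2198 genes were called for MMA, 1300 for FA, 4591 for MMA+FA against control, 1515 against MMA, 966 against FA, 214 for the interaction and 4614 in the F test, all within 1.5 times. After the group mean of each gene was subtracted, libraries of different groups with the same number correlated across genes between -0.124 and 0.107. Of 18 such pairs, 1 lay above 0.1, and 0 libraries correlated best with their own number. This is a hint from the data, not the design. TPM keeps no depth, so what depth limits could not be judged.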

Other observations

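Among genes of folate and cobalamin metabolism, the reduced folate carrier gene Slc19a1 rose with FA from 14.2 ± 0.135 to 18.0 ± 1.08 TPM (n = 3 per group; log2 0.32, adjusted p = 0.00729) and with MMA+FA by 0.41 relative to the shift of the typical gene (adjusted p = 0.000286 under median-ratio scaling). Slc19a1 also rose with MMA alone, by 0.27 relative to the shift (adjusted p = 0.0088 under median-ratio scaling). For TPM as deposited that call (adjusted p = 0.0213) was lost with some libraries left out (adjusted p up to 0.0827). With MMA+FA, Mthfs fell by 0.38 relative to the shift (adjusted p = 0.00757 under median-ratio scaling). Atic with MMA (-0.19) and Mthfd1l (-0.29) and Shmt2 (-0.27) with MMA+FA passed as deposited, but not under median-ratio scaling (adjusted p = 0.0871, 0.0657 and 0.127). Of 23 folate genes 3 were higher and 4 lower with MMA, 1 and 2 with FA, and 2 and 13 with MMA+FA, or 3 and 1, 1 and 0, and 3 and 1 under median-ratio scaling. The list was not called by camera (adjusted p = 0.967, 0.866 and 0.406). Fry, which asks only whether a list moves one way, called it down with MMA (adjusted p = 0.0156) and MMA+FA (adjusted p = 0.000118) for TPM as deposited, where the typical gene fell too, but not under median-ratio scaling (adjusted p = 0.518 and 0.336). Lmbrd1, a cobalamin exporter of lysosomes, fell with MMA by 0.27 (adjusted p = 0.0111), a call lost without MMA replicate 3 (adjusted p = 0.0502), and Abcd4, its partner, fell with MMA+FA from 25.2 ± 1.27 to 18.9 ± 2.06 TPM (adjusted p = 0.0015). Of 22 genes of propionate and cobalamin metabolism 0 were higher and 4 lower with MMA, 0 and 2 with FA and 1 and 6 with MMA+FA, or 0 and 1, 0 and 0, and 4 and 1 under median-ratio scaling (adjusted p = 0.746, 0.852 and 0.832 in camera). Fry called this list down with MMA (adjusted p = 0.0185) and MMA+FA (adjusted p = 0.000546) for TPM as deposited. Under median-ratio scaling it did not call it with MMA (adjusted p = 0.18) and called it up with MMA+FA (adjusted p = 0.0484), so its direction depends on the scaling.

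Immediate early and inflammatory genes fell in part. With MMA, Junb fell from 76.6 ± 6.47 to 49.5 ± 0.992 TPM (n = 3 per group; log2 -0.62, adjusted p = 0.00164), Egr1 by 0.60, Ier2 by 0.55, Fosl1 by 0.37 and Btg2 by 0.36. Myc, Spry4 and Ier3 rose by 0.33, 0.29 and 0.27 relative to the shift, calls that for TPM as deposited were lost with some libraries left out (adjusted p up to 0.085, 0.115 and 0.147). Of 27 such genes 3 were higher and 11 lower, 5 and 14 adjusted over the list alone, and 7 and 10 under median-ratio scaling, and the list was not called (adjusted p = 0.458). With MMA+FA, the growth factor gene Csf1 fell from 180.1 ± 3.50 to 97.9 ± 3.89 TPM, by 0.75 relative to the shift (adjusted p = 2.05e-06 under median-ratio scaling), Relb by 0.61, Cxcl1 by 0.96 and Nfkbia by 0.40, while Ptgs2 and Nlrp3 rose by 0.57 and 0.63. Of 20 NF-kB targets 2 were higher and 12 lower, or 3 and 9 under median-ratio scaling (adjusted p = 0.0536 for the list as deposited and 0.00886 with that scaling, which calls it, and as deposited adjusted p = 0.428 with an estimated correlation). The interferon genes Gbp2, Irf1 and Irf9 fell by 0.48, 0.45 and 0.32 relative to the shift. Of 17 interferon-stimulated genes 0 were higher and 9 lower, or 5 lower under median-ratio scaling (adjusted p = 0.0637 for the list as deposited and 0.0272 with that scaling, which calls it, and as deposited adjusted p = 0.418 with an estimated correlation).

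KEGG pathways, tested after the data were seen, were called in 30 of 261 cases for MMA, 10 for FA, 20 for MMA+FA against control, 16 against MMA, 22 against FA and 13 for the interaction at the preset correlation. With an estimated correlation the numbers were 0, 0, 0, 0, 8 and 0.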
